A study of Drosophila melanogaster with 6 samples.

How the data were processed

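Total RNA from *Drosophila melanogaster* embryos was measured on 6 Affymetrix Drosophila Genome 2.0 arrays, 3 from insv mutants and 3 from wild type. Per the labels, flies were kept and embryos aged at 25 °C, embryos were collected at 6 to 8 h, RNA was extracted with Trizol and the target was labelled with biotin. The deposited values are log2 expression levels made by the authors with GCRMA, per the submitters' processing notes, and the version is not given in the sources used here. GCRMA is a method that corrects background with a model of probe sequence, makes arrays comparable and summarises each probe set as 1 value. The log2 scale was read from the values, which ran from 2.2 to 15.1 on every array with 1 decimal. They were not centred, since array medians were 2.4 on each wild-type and 2.5 on each mutant array. Which options of GCRMA were used, and at which step the values were rounded, stays unknown.

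The value table held 18952 probe sets. The 183 control probe sets were left out of the tests and read separately. Of the other 18769, 13647 had 1 gene symbol in the platform annotation, 402 had several and 4720 had none. Symbols were updated through the gene identifier for 13544 probe sets, using the RefSeq annotation of assembly Release 6 plus ISO1 MT, which served only for names and for the order of neighbouring genes. Genes were not named from probe sets with several symbols. Every column belonged to a labelled sample.

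GCRMA places unexpressed probe sets near a floor, and between 45.86% and 46.14% of probe sets lay at 2.2 on an array. Probe sets with a value of at least 4 on at least 3 of the 6 arrays, whatever the genotype, were tested. This left 8334 probe sets, 7356 of them with 1 symbol, 226 with several and 752 with none. They stood for 6932 genes, each represented by its probe set with the highest mean over the 6 arrays. The filter and the floor mean that a fold change against a gene near 2.2 understates the difference. The number of arrays limits the precision.

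Mutant and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, no block). Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets. Rounding to 1 decimal left 24.1% of tested probe sets with identical values on all 3 arrays of at least 1 genotype, and the prior degrees of freedom were estimated at 1.18. Gene lists were compared with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists with at least 5 tested members, and again with a correlation estimated per list. Limma's fry was run beside it. Fry asks whether the members of a list move on balance one way and does not compare the list with other genes. The 30 lists of marker and pathway genes, the ribosomal protein genes, and the 10 nearest annotated genes on each side of insv made 32 lists, written from textbook knowledge before the data were examined. Members for which the annotation used gave no uniquely named probe set were not analysed here, among them several core genes of the Notch pathway.

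The genes named were chosen by a rule fixed before the data were examined. It took insv, the 12 largest positive and 12 largest negative log2 fold changes among called genes whose mutant and wild-type values did not overlap, and all tested members of the E(spl) bHLH, Bearded and proneural lists. It added up to 4 members of each other list with the smallest adjusted p (2 of the highest mean where none passed) and the 4 nearest measured genes on each side of insv. Genes named outside the rule are marked as chosen after their values were seen.

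The labels call the 3 samples of a genotype replicates and do not say whether they came from separate collections. The p-values therefore measure only the spread between these samples, which may be technical. No 2 arrays held identical values: the closest pair of 1 genotype agreed at 43.1% of tested probe sets.

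On simulated data with the spread of the 8334 tested probe sets and 200 changed ones, the test called 88% of the 2-fold changes and 55% of changes of 0.5 on the log2 scale. Of its 151 calls, 8 (5.3%) were false. A list shifted by 0.3 in a second simulation was called and 0 other lists were. In the data 5459 probe sets were called, many more than the 200 simulated, so these error rates need not hold there. On the real arrays, other splits into 3 and 3 called 0 probe sets but 3 to 9 lists with camera. These splits mix the genotypes, so the genotype difference enters their spread and their counts do not measure false calls.

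The alternatives were no filter, a filter at 6, quantile normalization, centring of arrays on their median, a trend or a robust prior, array weights, the replicate number as a block, and each array left out in turn. Further ones were a minimum fold change, 1 probe set per gene, a test per probe set without pooled variance, and, for lists, an estimated correlation, fry and the mean of a gene's probe sets. Noise within the rounding interval, scaling to the spike-in probe sets and camera on ranks were added after the data were seen.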

Results

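Insensitive (insv) encodes a nuclear BEN-domain protein of neural precursors that represses transcription and binds Suppressor of Hairless, the DNA-binding factor of the Notch pathway. Expression was profiled in embryos of 6 to 8 h carrying an insv mutant allele and in wild-type embryos, with 3 arrays per genotype. The comparison asks which transcripts differ when the gene is mutated. Between 7821 and 7883 probe sets reached a log2 level of 4 on the wild-type arrays and between 8295 and 8312 on the mutant arrays. Arrays of 1 genotype were nearly superimposable, with correlations across tested probe sets of 0.996 to 0.998, and the SD of their differences was 0.131 to 0.229 on the log2 scale. Between genotypes the correlation was 0.905 to 0.906 and the SD of differences 1.07 to 1.09. These correlations are across probe sets, which are not independent replicates.

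The mutated gene itself was nearly lost from the mutant arrays. The insv probe set read 10.90 ± 0 in wild type and 3.93 ± 0.31 in the mutant (log2 level, mean ± SD, n = 3 each), a log2 fold change of -6.97 ± 0.16 (SE; limma adjusted p = 3.26e-06), or 125-fold lower. All 3 mutant values (4, 3.6 and 4.2) lay far under the wild-type value of 10.9 on each array, so the genotype labels matched the level of the gene. Whether its probes lie inside the mutated part is not given in the sources used here. The adjacent gene Elba2, which encodes another BEN-domain factor, read 6.33 ± 0.15 in wild type and 2.47 ± 0.12 in the mutant, close to the floor of 2.2 (log2 fold change -3.87 ± 0.10 SE, adjusted p = 4.94e-06). The next genes on that side differed little. ND-B17.2, a subunit gene of mitochondrial complex I, had a log2 fold change of 0.10 (adjusted p = 0.162). Arpc5 (-0.27, adjusted p = 0.0196) and Drp1 (-0.13, adjusted p = 0.0231) passed the threshold, but both lost it after quantile normalization (adjusted p = 0.0615 and 0.334) and whenever 1 of the 3 mutant arrays was left out. On the other side CG3528, CG3515 and Cyp309a2 lay at or beside the floor in both genotypes. Cyp309a1 read 3.93 ± 0.21 in the mutant and 2.4 ± 0 in wild type, under the filter, and was not tested.

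Across the transcriptome, increases outnumbered decreases among the large differences. A change of at least 2-fold was called for 1353 probe sets, 1062 higher and 291 lower in the mutant. After quantile normalization these numbers were 922 and 592, and on a scale set by the Bacillus spike-in controls 7241 and 35. At least 16-fold changes numbered 116, of which 100 were higher. Without a minimum fold change, 5459 of 8334 probe sets (65.5%) were called, 2055 higher and 3404 lower, because small falls were numerous: the median log2 fold change was -0.10, with quartiles of -0.37 and 0.20. Centring each array on its median gave 51.5% of calls as higher, against 37.6% on the deposited scale. In 5463 tested probe sets the mutant and wild-type values did not overlap, where chance gives 10%.

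The strongest increases included several enzymes and secreted proteins. Mal-A3, a maltase, rose by 5.40 ± 0.06 (log2 fold change ± SE), Cyp6g1, a cytochrome P450 linked to insecticide resistance, by 5.23 ± 0.12, Obp56d, an odorant-binding protein, by 5.13 ± 0.23 and LManVI, a lysosomal alpha-mannosidase, by 4.97 ± 0.10. The others among the 12 were genes known by number, from CG33272 (6.17 ± 0.22) and CG18754 (6.13 ± 0.06) to CG13043 (4.93 ± 0.12). The strongest decreases were Cyp6d2, another cytochrome P450, at -7.93 ± 0.14 and CG13689 at -7.07 ± 0.09, ahead of insv. Ccdc85 (-5.27 ± 0.19) and CG14111 (-4.97 ± 0.06) were also among them, and so was CG43090, whose difference of -5.20 is only a bound, because all 3 mutant values lay at the floor of 2.2. Mastermind (mam), a coactivator of Notch-dependent transcription, fell from 7.47 ± 0.32 to 2.57 ± 0.15 (SD, n = 3 each; -4.90 ± 0.18 SE), and the leucokinin receptor gene Lkr fell by 4.37. The mam and Lkr values each rest on 1 probe set. Adjusted p lay between 4.37e-07 and 0.000185 for the genes of both groups of 12 (limma).

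**Figure D1:**
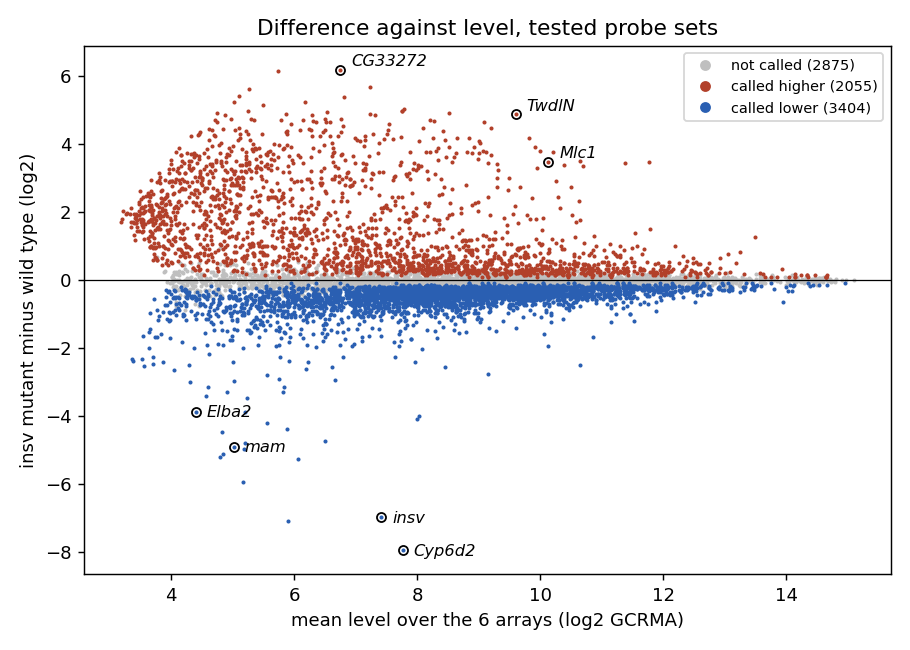
Each point is 1 of the 8334 tested probe sets, with its mean log2 GCRMA level over the 6 arrays on the x axis and the log2 difference, mutant minus wild type, on the y axis; red points were called higher (2055), blue points lower (3404) and grey points were not called, and 7 genes are circled. Large differences are mostly above 0, while insv (-6.97), Cyp6d2 (-7.93), mam (-4.90) and Elba2 (-3.87) stand apart below it.

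Signals of control probe sets that hold no fly RNA also differed with genotype, and the cause was not tested. The 23 probe sets for Bacillus spike-in transcripts, which hold no fly RNA, were lower on all mutant arrays than on all wild-type arrays, by a median of -1.43 (range -1.77 to -0.90, log2). The 18 probe sets for bacterial and phage hybridization controls had a median of -0.55, and 16 of them did not overlap between genotypes. All arrays of a genotype shared this difference, so no comparison within a batch could be made, and array handling and genotype cannot be told apart. On a scale that equalises the Bacillus spike-ins, the median log2 fold change moves from -0.10 to 1.43 and 2987 of the 3404 falls are called as rises. It is only 1 possible scale, since the hybridization controls ranged from -1.80 to -0.17 and 1 constant shift does not equalise all controls. On that scale at most 1 tested member of any gene list is called lower. The 5′ minus 3′ signal was alike in the genotypes. For actin it was -3.03 ± 0.15 in wild type and -3.03 ± 0.06 in the mutant (log2, SD, n = 3 each). For eIF-4a it was -4.03 ± 0.06 in wild type and -3.97 ± 0.15 in the mutant. The 5′ signal was far lower in both genotypes, so these values compare the genotypes and do not show that RNA was intact.

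Targets of Notch signalling, the pathway in which Insv has been placed, differed little on the deposited scale. Of the 5 tested bHLH repressor genes of the E(spl) complex, which shut down neural fate in cells receiving Notch signal, only E(spl)mbeta-HLH passed (-0.37 ± 0.09 SE, adjusted p = 0.0135), and its adjusted p was 0.0518 to 0.0528 when mutant replicate 2 or 3 or wild-type replicate 1 or 2 was left out. E(spl)m7-HLH (0.07), E(spl)mdelta-HLH (0.07), E(spl)m3-HLH (0.13) and E(spl)m5-HLH (-0.10) did not pass. After median centring 3 of the 5 were called higher and 1 lower, and on the spike-in scale all 5 were higher (median 1.60), as were all 7 of the Bearded family (median 1.47). In the Bearded family, small antagonists of Notch ligand activity, BobA (-0.27, adjusted p = 0.00492) and Ocho (-0.23, adjusted p = 0.0218) fell among 7 tested. The Ocho call was lost after median centring (adjusted p = 0.116) and without mutant replicate 1, 2 or 3 or wild-type replicate 1 (adjusted p = 0.0521 to 0.0686). The remaining members, Brd, Tom, E(spl)m4-BFM, E(spl)m2-BFM and E(spl)malpha-BFM, ranged from -0.07 to 0.00. Neither list was called (camera adjusted p = 0.858 and 0.825). Of 20 Notch pathway components, 2 were higher and 6 lower (camera adjusted p = 0.825). Besides mam these included fng, which modifies the receptor with sugars (0.60), O-fut1, which acts in the same modification (-0.67), and Psn, the protease that cleaves the receptor (-0.20).

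Proneural bHLH genes, which start neural fate, were slightly lower in the mutant. Of 8 tested, 7 fell and da did not pass (0.03). The falls were small for ac (-0.43), sc (-0.40), ato (-0.40), l(1)sc (-0.37), ase (-0.30) and tap (-0.13), and larger for cato (-1.53 ± 0.20 SE, adjusted p = 0.0018). The ase and tap calls were lost after median centring (adjusted p = 0.0528 and 0.455), and that of tap also after quantile normalization (adjusted p = 0.11) and without wild-type replicate 1 or 2 (adjusted p = 0.06 and 0.0522). With a median of -0.38 (1.15 on the spike-in scale) the list missed the threshold against other genes (camera adjusted p = 0.092), and 7 passed when adjusted over the list alone. Camera called the list without the filter on low values. Fry, which tests the list by itself, gave an adjusted p of 0.000103. Among 15 sensory organ precursor genes 7 fell, including meru (-0.57), Poxn (-0.47) and insc (-0.30), and 0 rose on the deposited scale (median -0.20, or 1.33 on the spike-in scale, camera adjusted p = 0.45). In this list 3 were higher and 7 lower after quantile normalization, and 3 higher and 5 lower after median centring. Of 29 neuroblast genes 4 were higher and 11 lower, with grh at 0.40, gsb at -0.47, pdm2 at -0.40 and pins at -0.37 (camera adjusted p = 0.858). Median centring turned this balance to 7 higher and 5 lower, and on the spike-in scale all 29 were higher. Adjusted over the list alone, 7 sensory organ precursor and 14 neuroblast genes passed.

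Genes of terminal differentiation, switched on in late embryos, were far higher in the mutant. All 23 tested members of the late embryonic list rose, 20 of them at least 2-fold, with a median log2 fold change of 2.97. They included the myosin light chain gene Mlc1 (8.40 ± 0 in wild type, 11.87 ± 0.06 in the mutant, SD, n = 3 each; 3.47 ± 0.04 SE), the cuticle genes Cpr56F (3.67 ± 0.04) and TwdlM (3.90 ± 0.05), and Osi6 of the Osiris family (2.73 ± 0.05). The 10 muscle genes of this list had a median of 3.37 and its 12 cuticle and epidermal genes one of 2.5. Camera gave an adjusted p of 6.73e-14, and an adjusted p of 0.0799 with an estimated correlation. The epidermal and cuticle list, 9 of whose tested genes are also in the late list, had 21 of 25 members higher and 0 lower (19 and 1 after quantile normalization), with TwdlN at 4.87 ± 0.05 and a median of 1.5 (camera adjusted p = 1.78e-09, and 0.104 with an estimated correlation as adjusted p). Without the shared genes 12 of 16 were higher, with a median of 0.55. The filter keeps a gene that is low in wild type only if it is higher in the mutant: without it 23 of 34 late genes (median 1.92) and 21 of 35 epidermal genes (median 0.67) were higher, and 0 were lower.

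Lists for neurons, gut, mesoderm and trachea held both strongly higher genes and genes that differed little, and the mesoderm list also held a strongly lower one. Of 24 neuronal differentiation genes 10 rose and 4 fell, with a median of 0.02 and a mean of 0.96 (11 and 8 after quantile normalization). The rises included Gad1, which makes the transmitter GABA (3.87), the synaptic genes Rab3 (3.63) and cpx (3.47), and the sodium pump subunit gene nrv3 (3.37). Of 15 endoderm and gut genes 7 rose at least 2-fold and 1 fell (median 0.10), with the digestive genes Mal-A3 (5.40), alphaTry (4.40) and Jon25Biii (4.37) and the gap junction gene Inx7 (2.03) among the rises. Of 30 mesoderm and muscle genes 14 rose and 9 fell. Contractile genes such as Tm2 (3.67), Mlc2 (3.30) and Prm (2.97) were among those that rose. The largest fall in this list was that of sns, which acts in myoblast fusion (7.13 ± 0.25 in wild type, 3.27 ± 0.25 in the mutant, SD, n = 3 each; -3.87 ± 0.18 SE, adjusted p = 3.78e-05), named after its value was seen. The 21 genes not in the late list had a median of -0.10. Of 14 tracheal genes 6 rose, including the chitin-modifying genes Gasp (1.83), serp (1.8) and verm (1.70), and 0 fell. The tracheal list shares 3 tested genes with the late list, and Gasp is also in the epidermal and cuticle list. Another of the 6, knk (0.40), was lower after quantile normalization (-0.36, adjusted p = 0.00489), which left 5 higher and 1 lower. The neuronal, gut, mesoderm and tracheal lists did not pass (camera adjusted p = 0.0592, 0.0543, 0.0592 and 0.0611), but all 4 were called without mutant replicate 1 or without wild-type replicate 3, where 9 lists passed in place of 5. All 4 were also called without the filter and by fry, and none with an estimated correlation. The mean of a gene's probe sets called the neuronal, gut and mesoderm lists, and quantile normalization called the gut list. Adjusted over the list alone, 14 neuronal, 8 gut, 23 mesoderm and 6 tracheal genes passed.

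The hemocyte list, markers of blood cells, had 8 of 16 members higher, 3 lower (1 of them at least 2-fold) and 5 not called (median 0.33). Basement membrane genes led it, namely Glt (4.30), vkg (3.80) and Col4a1 (3.57), the last pair encoding type IV collagen. Its camera adjusted p was 0.0422, with an adjusted p of 0.506 under an estimated correlation, and the call was lost without mutant replicate 3 (adjusted p = 0.063) or wild-type replicate 1 (adjusted p = 0.0597), with the replicate number as a block (adjusted p = 0.0631) and with camera on ranks (adjusted p = 0.0502). Among detoxification genes 26 of 36 rose and 7 fell, with a median of 2.00. Cyp6g1 (5.23), Cyp4e2 (3.77), Cyp9b2 (3.70) and the glutathione transferase GstD3 (2.17) rose. Camera gave this list an adjusted p of 2.18e-06, and an adjusted p of 0.506 with an estimated correlation. Without the filter 8 of 21 hemocyte genes (median 0.10) and 28 of 60 detoxification genes (median 0.25) were higher. Adjusted over the list alone, 23 late embryonic, 21 epidermal, 11 hemocyte and 33 detoxification genes passed. The spike-in difference of -1.43 was shared by the same arrays but ran opposite to the rises of these 4 lists. On the spike-in scale their medians were larger, at 4.5 (late embryonic), 3.03 (epidermal), 1.87 (hemocyte) and 3.53 (detoxification). That scale moves all genes of an array by 1 constant, so the median of every list rises alike (ribosomal protein genes from 0 to 1.53). The larger medians and the opposite direction therefore do not argue against a batch.

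**Figure D2:**
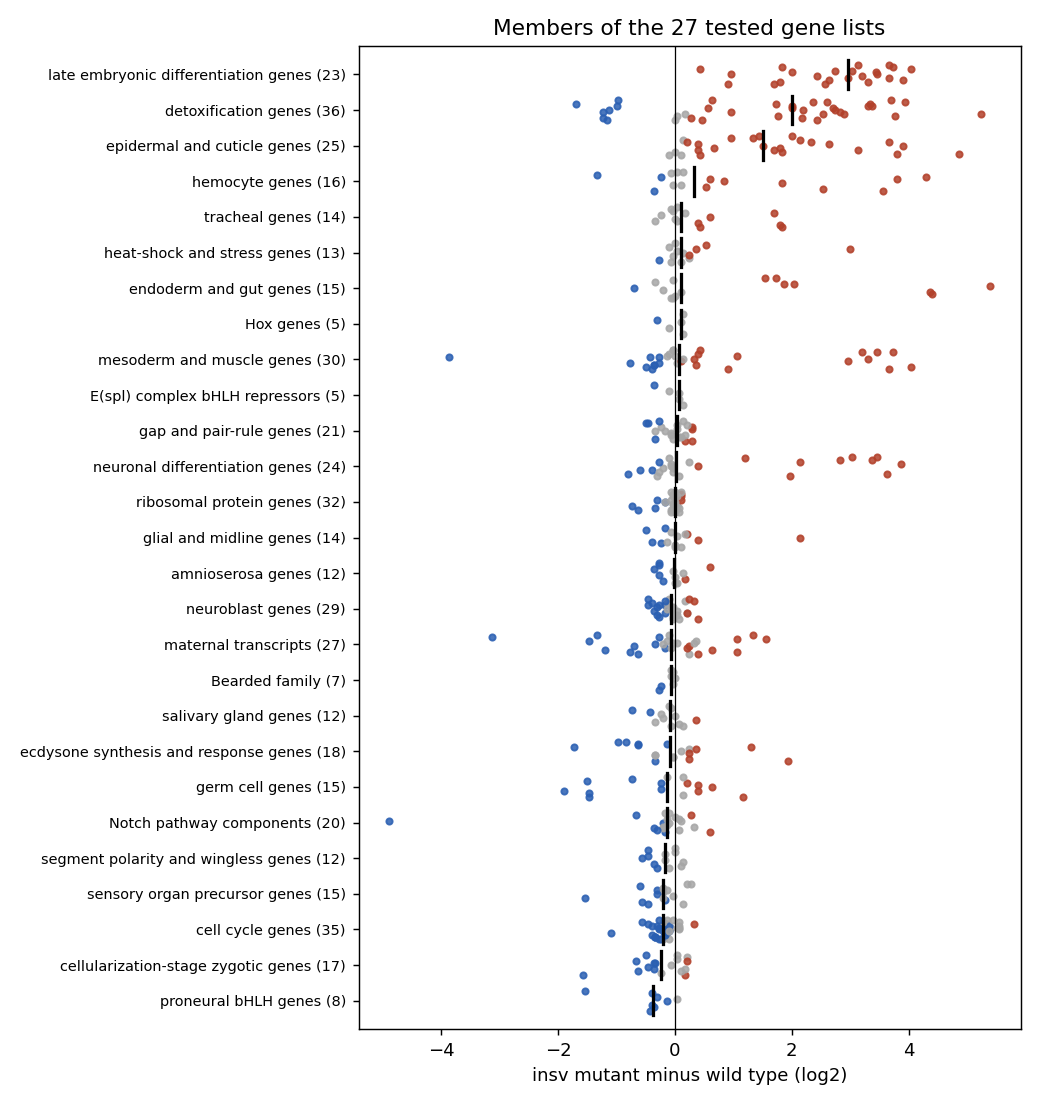
Each point is the log2 difference, mutant minus wild type, of 1 tested gene in the 27 gene lists with at least 5 tested members (number tested in parentheses), in red where called higher, blue where called lower and grey where not called; black bars are list medians. The late embryonic list lies wholly above 0 (median 2.97), the neuronal, gut and muscle lists hold a group of strongly higher genes beside medians of 0.02 to 0.10, and the proneural list has the lowest median (-0.38).

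Cell cycle genes moved the other way on the deposited scale, by little more than genes in general. Over all 6932 genes the median was -0.13 and 2891 were called lower. On the spike-in scale 34 of the 35 tested cell cycle genes were called higher and 0 lower. Of 35 tested 21 fell, 1 of them at least 2-fold, and 1, Rbf2 (0.33), rose (median -0.20, or 1.33 on the spike-in scale), and after median centring 12 fell. Falling members included pim (securin, -0.47), mad2 of the spindle checkpoint (-0.33) and CycD (-0.57), and the fall of at least 2-fold was that of cid, the centromeric histone (-1.10 ± 0.13 SE, adjusted p = 0.00127), named after its value was seen. The camera adjusted p was 0.0407, the adjusted p with an estimated correlation was 0.506, and the call was lost after quantile normalization (adjusted p = 0.176) and with noise added within the rounding interval (adjusted p = 0.0705). Adjusted over the list alone 24 passed.

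In lists of earlier stages and of the embryonic pattern the members moved both ways or little, and camera called none of these lists. Fry, which tests each list by itself, gave adjusted p of 0.0053 for the cellularization-stage, 0.00319 for the segment polarity and 0.000162 for the germ cell list, each on balance lower. Among 17 cellularization-stage genes 8 fell and 2 rose, with slam at -1.57 and Sry-alpha at -0.67 (median -0.23, camera adjusted p = 0.825). Of 27 maternal transcripts 8 were higher, including mtrm (1.33) and spz (1.07), and 10 lower, including tor (-1.47) and bcd (-1.20), with a camera adjusted p of 0.858. The largest fall in this list was that of plu (-3.13, adjusted p = 0.000166), named after its value was seen. Germ cell genes were split as well, 5 of 15 higher and 7 lower, with a camera adjusted p of 0.921. At least 2-fold, 4 fell, among them piwi (-1.50) and AGO3 (-1.47), and 1 rose. A smaller rise was that of osk (0.63). Of 21 gap and pair-rule genes 4 rose and 4 fell, with ftz at -0.50 (camera adjusted p = 0.825). In the segment polarity list 5 of 12 fell, including hh (-0.47) and inv (-0.57), and 0 rose (camera adjusted p = 0.497). In the Hox list only Dfd of 5 passed (-0.30, camera adjusted p = 0.858). These counts depended on the scale: after median centring they were 5 higher and 7 lower for cellularization-stage genes, 11 and 8 for maternal transcripts, 7 and 5 for germ cell genes, 8 and 2 for gap and pair-rule genes, 2 and 4 for segment polarity genes and 2 and 1 for Hox genes. Quantile normalization moved germ cell genes the other way, to 5 higher and 9 lower, and their median from -0.13 to -0.54. The list median, mean and camera direction differed in sign for the E(spl), gap and pair-rule, Hox and maternal lists.

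**Figure D3:**
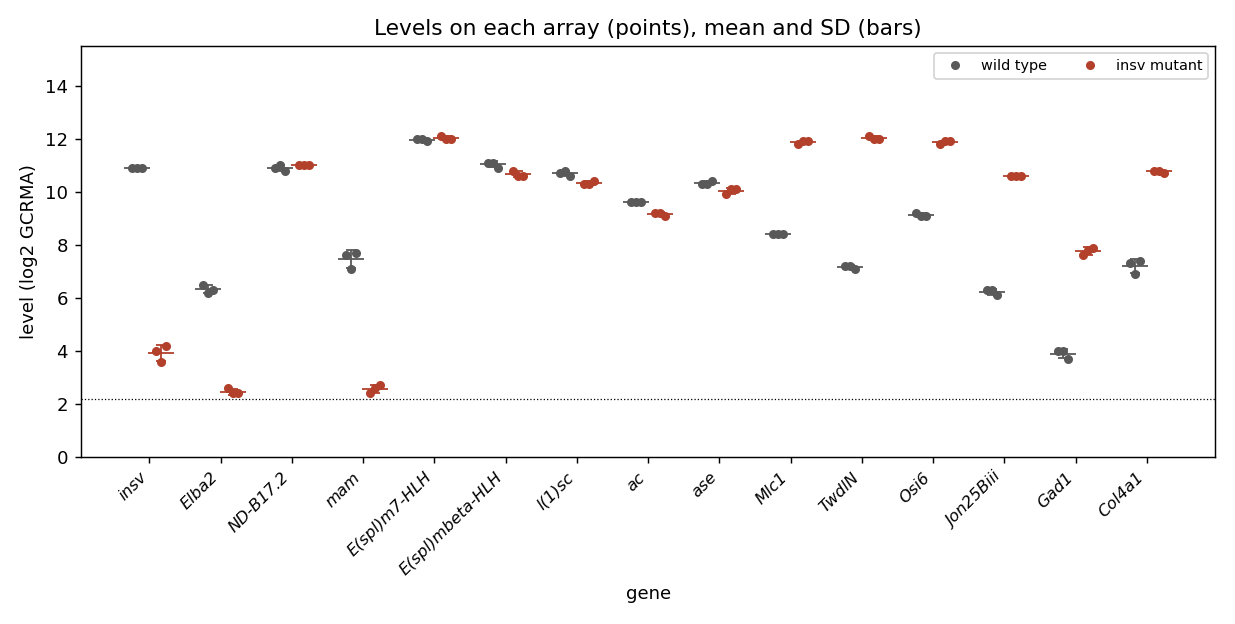
Log2 GCRMA levels of 15 genes on each of the 3 wild-type (grey) and 3 mutant (red) arrays are shown as points, with horizontal bars for the mean and error bars for the SD; the dotted line is the floor of 2.2. Levels of insv, Elba2 and mam drop toward the floor in the mutant, E(spl)m7-HLH differs by 0.07, and Mlc1, TwdlN, Osi6, Jon25Biii, Gad1 and Col4a1 are higher on each mutant array than on each wild-type array.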

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

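The tests of a batch shared by the arrays of a genotype and of older animals among the mutant embryos were chosen after the values they rest on had been seen. The test of probe sequence was written once the genes concerned were known, but before their other probe sets were looked at.

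Among the control probe sets, which were left out of the tests, 6 gave signals more than 2-fold higher in the mutant with no overlap between the genotypes. Of these, 5 GAPDH controls were higher by 2.63 (3′ end), 2.70 (5′ end), 2.77 (middle), 1.30 and 1.60 (a second design, 3′ end and middle) on the log2 scale, while 2 further GAPDH controls of the second design differed by 0.27 each, 1 without overlap (5′ end) and 1 with overlap (3′ end), and the 3′ controls of actin and eIF-4a differed by 0.03 and -0.13. The remaining control read 6.60 in the mutant and 2.27 in wild type, a difference of 4.33. Its target is not given in the sources used here and need not be a fly gene, so the value cannot be read as a change of a fly transcript.

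The first pattern is the number of calls, 5459 of 8334 probe sets. The 9 other splits of the 6 arrays called 0 each with limma (8 to 254 at an unadjusted p under 0.05, against 5787), and the real split was the only 1 of 10 to reach its count. Each other split mixed the genotypes, so the difference between genotypes entered its spread and held its calls down. The 0 calls therefore do not show how many calls chance would give. In any case 10 splits are too few for a share under 0.05. Sequence or expression differences carried along with the insv locus would place calls near it. Of the 100 nearest tested genes (50 on each side) 71 were called, against 4548 of 6831 others. The odds ratio was 1.23 (95% interval 0.785 to 1.97, one-sided Fisher's exact p = 0.206), with the upper end just under the bound of 2 set beforehand. By that bound, calls were not concentrated near the locus to an odds ratio of 2 or more. The source of calls elsewhere is not addressed, because 100 genes could not hold most of the calls. Linkage stays open for falls of at least 2-fold, with 6 of 100 near genes against 3.25% of the others (odds ratio 1.9, 95% interval 0.673 to 4.36). A labelling or hybridization batch remains open: the Bacillus spike-ins differed by -1.43 with no overlap, a value that prompted this explanation and so cannot test it. Batch, strain background away from the locus and the mutation itself cannot be told apart here, because each genotype's arrays share all of them.

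The second pattern is the rise of late embryonic genes. Mutant embryos that were older as a whole might also have lost early transcripts; the cellularization-stage list had a median of -0.23, inside the range of random lists matched on level (-0.33 to 0.10), so that test left the question open. Maternal transcripts (median -0.07) lay inside the range of their random lists (-0.27 to 0.07). Gap and pair-rule genes (0.03) lay just above theirs (-0.33 to 0, percentile 99.5), whereas a loss of early transcripts would place them low. These 2 lists do not settle the question, because members of both moved both ways and 8 of the 17 cellularization-stage genes fell. Older animals mixed into the mutant collections stay open and untested. The lowest median among the parts of the late list was 2.5 (cuticle), but the neuron part was only 1 tested gene, ChAT (3.03). Its neuronal genes brp, nSyb, para and VGlut lay under the filter in both genotypes and were not tested. The same held for cuticle genes such as Cpr47Ef and Edg78E (all these genes named after their values were seen). All 23 tested members were already known to be higher, so no part could have come out otherwise. Loss of repression by Insv is the biological explanation that the design offers, and it stays untested, because binding sites were not used here. The adjacent BEN-domain gene Elba2 was also lower in the mutant (-3.87), so an effect of insv alone cannot be told apart from that difference.

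The count of called lists, 5, was reached or passed by 5 of the 10 splits with the real one included, and the highest other split gave 9. The other 4 of these splits called 0 probe sets, so the number of lists did not set the real grouping apart. Each of them mixes the genotypes unevenly and still holds part of the genotype difference, which camera can pick up. Their counts therefore do not show how many lists chance would give. In any case 10 splits are too few for a share under 0.05.

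The third pattern is all-or-none differences: 12 probe sets with a mean of at least 7 in wild type lay under 4 on every mutant array, mam, Ccdc85, Lkr and sns among them, and 48 showed the opposite. Sequence differences under the probes between the strains could produce some of them, and a second probe set of the same gene would tell. Of these genes, 0 had another tested probe set, so the test of sequence differences under the probes could not be carried out and the question stays open.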

How the results depend on the processing

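Scaling to the spike-ins, noise within the rounding interval and camera on ranks were chosen after seeing the data. The causes of the changes given here were not tested unless the setting itself sets them. Requiring a 1.5-fold change left 2321 calls (1353 higher, 968 lower) and a 2-fold change 1353 (1062 higher, 291 lower), by construction. Quantile normalization raised the falls of at least 2-fold from 291 to 592. Scaling to the spike-ins gave 7916 probe sets higher and 50 lower (99.4% of calls higher), with 7241 higher and 35 lower among 7276 changes of at least 2-fold. Calls numbered 3932 to 6500 under the other settings, and 4710 to 5713 with 1 array left out. Median centring kept 4489 of the 5459 calls in the same direction and turned 0; quantile normalization kept 4821 and turned 24. The log2 fold change of insv ranged from -7.29 to -6.80. After quantile normalization knk went from 0.40 to -0.36 and PGRP-SC2 from 0.57 to -0.12.

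In place of 5 lists, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05), 17 with fry, 11 without a filter, 8 with the mean of a gene's probe sets, and 4 to 9 with 1 array left out (9 without mutant replicate 1 or wild-type replicate 3). The late embryonic, epidermal and detoxification lists passed under each of these except the estimated correlation.

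Whether the replicate numbers pair the arrays was not settled. Deviations of same-numbered arrays correlated at 0.166, -0.0145 and 0.271, the last being the highest value between genotypes. Mutant replicate 1 correlated better with wild-type replicate 2 (0.197) than with wild-type replicate 1. Deviations from a mean of 3 arrays are tied to each other, so these values cannot exclude a pairing. With the replicate number as a block, 5234 probe sets and 4 lists were called (the hemocyte list was lost, adjusted p = 0.0631) and insv stayed at -6.97 (adjusted p = 0.0012); of 124 named genes called, 3 lost the call. Signal near the floor of 2.2 limits the size of large changes.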

Other observations

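Gene families were also grouped by symbol, a grouping chosen after the data were seen, and tested among the increases of at least 2-fold. Of 42 families with at least 8 tested genes, 8 were enriched among increases (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). This test treats genes as independent, but genes of a family were measured on the same 6 arrays and may move together. Its p-values can therefore overstate the evidence. With a correlation estimated per list, camera called 0 gene lists, and the families were not tested that way. In the Cpr cuticle protein family 22 of 25 genes rose at least 2-fold (adjusted p = 2.9e-15), in the Tweedle family, also of cuticle, 14 of 15 (adjusted p = 1.42e-10), in the Osiris family 8 of 8 and in the Jonah family of gut proteases 9 of 10 (adjusted p = 1.02e-06 for both). Tetraspanins (13 of 20), cytochromes P450 (16 of 30), odorant-binding proteins (6 of 8) and UDP-glycosyltransferases (8 of 16) completed the group. Cytochromes P450 and UDP-glycosyltransferases also held genes at least 2-fold lower (4 of 30 and 2 of 16). The filter on low values drops members that are near the floor in both genotypes, which raises these shares. Without it, an alternative chosen after seeing the data, the counts were 22 of 66 for Cpr (adjusted p = 3.29e-07), 14 of 24 for Tweedle (adjusted p = 3.58e-08), 8 of 24 for Osiris (adjusted p = 0.00664), 9 of 13 for Jonah (adjusted p = 2.44e-06), 17 of 32 for tetraspanins (adjusted p = 8.21e-09) and 19 of 83 for cytochromes P450 (adjusted p = 0.000755). UDP-glycosyltransferases (8 of 35, adjusted p = 0.0709) and odorant-binding proteins (7 of 47, adjusted p = 0.501) no longer passed, and GstD and obst came in, so that 8 of 77 families passed. Of 44 mRpL genes of the mitochondrial ribosome 0 were called with a 2-fold change in either direction (median -0.20, against -0.10 over all tested probe sets). For decreases of at least 2-fold 0 families were enriched (2 at an unadjusted p under 0.05), and the lowest adjusted p was 0.203 (GstE, 3 of 11 lower, unadjusted p = 0.00482), followed by 0.34 (Cyp, unadjusted p = 0.0162).

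Lists for other tissues and states gave mixed values. Of 18 ecdysone genes 5 were higher and 7 lower: dib (-1.73) and sad (-0.97), which make the hormone, fell and Cyp18a1 (1.30), which breaks it down, rose (camera adjusted p = 0.906). Among 13 heat-shock and stress genes 4 rose and 1 fell, with stv at 3.00 (camera adjusted p = 0.207). Of 14 glial and midline genes 3 rose and 4 fell (ine 2.13, gcm -0.23), of 12 amnioserosa genes 2 rose and 5 fell (tok 0.60, tup -0.27) and of 12 salivary gland genes 1 rose and 2 fell (sage -0.73), with camera adjusted p of 0.858, 0.906 and 0.858, and the glial list had 4 higher and 3 lower after quantile normalization and after median centring. Of 32 ribosomal protein genes 3 rose and 5 fell (median 0, camera adjusted p = 0.865), but 14 rose and 3 fell after median centring and 1 rose and 6 fell after quantile normalization. Median centring also moved the ecdysone list to 6 higher and 6 lower, the amnioserosa list to 3 and 3 and the salivary gland list to 2 and 2, and quantile normalization gave 3 and 7 for the ecdysone and 5 and 3 for the heat-shock list. Lists with fewer than 5 tested genes had no list test: 3 of 3 immune genes rose (PGRP-SC2 0.57, Rel 0.40, Tep4 0.30) but 2 of 3 after quantile normalization, where PGRP-SC2 read -0.12 (adjusted p = 0.178), 1 of 4 testis genes rose and 2 fell (bam -1.90, bol -0.80), 1 of 4 BEN-domain and partner genes fell (Elba2), and 3 of 4 tested nearest neighbours of insv fell (1 after quantile normalization, and 1 fell and 1 rose after median centring). Of the 19 ovarian and adult female genes with a probe set, 0 reached the level needed for testing.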
